A study of Mus musculus with 89 samples.

How the data were processed

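The forebrains of 89 mouse embryos at embryonic day 18.5 were measured on Clariom S high throughput arrays, with 1 array per embryo. According to the authors' processing notes, the deposited values are log2 probe set signals summarised by RMA, which corrects background, normalizes by quantiles and combines the probes of a set. The version and settings of RMA and the annotation of the array are not given in the sources used here. The 2 colonies lay at different levels, with median array means of 5.30 for the Ts65Dn colony and 6.39 for the Ts66Yah colony, so each genotype was compared only with euploid embryos of its own colony. The series text counts 25 Ts66Yah arrays and 90 in all, while it states 89 arrays and 24 are labelled Ts66Yah; the labels were followed.

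All 22206 probe sets were used without a filter on signal. Of these, 19572 carried 1 gene symbol and 2634 had no gene name in the table used here; unnamed probe sets were counted and not named. A reference gene table of the mouse genome was used for gene names and for the order of genes along Mmu16 and Mmu17. No genomic position is printed, because the build behind the array's annotation is not given in the sources used here. The number of arrays limits the precision of every value.

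Genotypes were compared with limma 3.58.1 in R 4.3.3 (linear model and eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 10%. The comparisons were Ts65Dn against EupTs65Dn, Ts66Yah against EupTs66Yah, the difference of these effects in 1 fit of all 89 arrays, EupTs65Dn against EupTs66Yah, and the interaction of genotype and sex in each colony. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The mean of the Mmu16 and of the Mmu17 list in each embryo was compared by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05. Calls shared by the models outside the triplicated parts were compared with the number expected by chance by a one-sided Fisher's exact test.

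The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 33 lists 29 were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and also with an estimated correlation and with fry. The Mmu16 and Mmu17 lists were tested by their means, the sex check genes were used for labels alone, and of 36 protocadherin alpha and gamma genes 0 were measured. Genes of the triplicated parts were taken out of the other lists and of camera's background, so that Olig1 and Olig2 do not count as oligodendrocyte markers.

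For each genotype comparison the rule took up to 10 Mmu16 and 10 Mmu17 genes with the smallest p among those past the threshold. It took up to 10 higher and 10 lower named genes outside both lists with the largest change, and up to 4 passing members of each other list, or its member with the smallest p where none passed. It always took App, Sod1, Dyrk1a, Olig1, Olig2, Rcan1, Ttc3, Dscam, Pcp4, Arid1b, Pde10a, Tulp4, Snx9 and Scaf8. For the euploid and sex comparisons it took up to 5 higher and 5 lower genes past the threshold. The text names a part of the list members this gives. Gpr31b, Unc93a, Tcp10b and Tcp10c were named after their values were seen.

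Labels were checked in 2 ways. An array counted as being at the level of the other genotype when its Mmu16 list mean lay nearer to the median of that genotype in its colony, which held for 4 arrays. The Y-linked genes Kdm5d, Uty and Eif2s3y went against the sex label in 17 arrays, and 1 array failed both checks. No label was changed and no array was left out of the main tests. For the low-spread array, 1 of the 17, the second check is uninformative. Settings chosen after seeing the data were to leave out the low-spread array, to leave out the 6 arrays of EupTs66Yah with a lower standard deviation than every Ts66Yah array, to leave out that array and the 4 arrays at the level of the other genotype, to leave out the 17 arrays whose Y-linked genes go against the sex label, array spread as a covariate, gene lists in the difference of effects and between the euploid groups, the litter as a block or array spread as a covariate without the low-spread array, and the means of other lists as covariates of a list mean.

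The alternatives fixed in advance were the litter as a block, sex as a covariate, the unpaired t-test of the series, a threshold of 0.05, the marginal criterion of the series (unadjusted p under 0.01 with a ratio under 0.8 or over 1.2), filters at the lower quartile and at the median of mean signal, quantile normalization, centring on the array median, array weights, a trended and robust prior, the first principal component of the residuals as a covariate, all 4 groups in 1 fit, and leaving out each litter in turn. Litters were not treated as pairs in the main tests. After subtracting each group's mean from the probe sets at or above the median signal, the median correlation of arrays of unlike genotype, without the low-spread array, was 0.042 within litters and -0.0078 between litters in the Ts65Dn colony, and 0.033 and -0.0092 in the Ts66Yah colony.

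The tests were tested on simulated data of the same sizes. The changed probe sets were drawn only from those at or above the median signal, so recovery among dimmer ones was not simulated. With 50 probe sets changed at each fold, limma recovered 62% of 1.2-fold and 92% of 1.3-fold changes in the Ts65Dn colony, where 15.0% of all calls were false. It recovered 8% and 56% in the Ts66Yah colony with all arrays (11.0% false), and 68% and 92% without the low-spread array (6.77% false). A shift of -0.15 over 20 simulated list members was recovered as -0.17 in the Ts65Dn colony and -0.20 in the Ts66Yah colony, with 0 other lists past the threshold of camera in either. The noise was drawn separately for each probe set. The simulation thus holds no correlation between genes and cannot show how often camera calls lists falsely in the data.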

Results

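The data are log2 expression values of the forebrain of 89 mouse embryos at embryonic day 18.5, with 1 array per embryo. Ts65Dn mice carry a small extra chromosome that joins a distal part of mouse chromosome 16 (Mmu16), rich in orthologues of genes on human chromosome 21 (Hsa21), to a proximal part of mouse chromosome 17 (Mmu17) whose genes are not Hsa21 orthologues. Ts66Yah mice were derived from Ts65Dn and lack the extra Mmu17 part. There were 18 euploid (EupTs65Dn) and 23 trisomic (Ts65Dn) embryos from 6 litters of the first colony, and 24 euploid (EupTs66Yah) and 24 trisomic (Ts66Yah) embryos from 6 litters of the second. Labels gave 9 females and 9 males in EupTs65Dn, 13 females and 10 males in Ts65Dn, 11 females and 13 males in EupTs66Yah, and 13 females and 11 males in Ts66Yah. The number of embryos limits the precision of every value.

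The mean log2 value of an array lay between 5.26 and 5.33 in Ts65Dn and between 5.29 and 5.31 in EupTs65Dn. It lay between 6.37 and 6.40 in Ts66Yah and between 6.05 and 6.41 in EupTs66Yah. EupTs66Yah replicate 16 had a standard deviation of 1.13 across its probe sets, against 2.23 to 2.39 in the other 23 arrays of that group. It is called the low-spread array here, and values for the Ts66Yah colony are given with and without it. EupTs66Yah replicates 9, 14, 17, 21 and 22 (2.23 to 2.27) also had a lower standard deviation than every Ts66Yah array (2.30 or more), and with the low-spread array they are called the 6 narrower arrays. The Mmu16 genes of 4 arrays lay at the level of the other genotype of their colony: those labelled Ts65Dn replicate 18, Ts66Yah replicate 13, Ts66Yah replicate 24 and EupTs66Yah replicate 24. All of them were kept under their labels.

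The first comparison asked which genes differ between Ts65Dn forebrain and that of euploid littermates. Genes of both triplicated parts were higher in Ts65Dn. The mean of 87 measured Mmu16 Hsa21 orthologues was 6.57 ± 0.089 (SD, n = 23) in Ts65Dn and 6.21 ± 0.042 (n = 18) in EupTs65Dn, a 1.29-fold difference (log2 0.36, SE 0.021). The mean of 42 measured proximal Mmu17 genes was 6.73 ± 0.093 against 6.41 ± 0.061, a 1.25-fold difference (log2 0.33, SE 0.024). Of the 87 Mmu16 genes 83 had a higher mean in Ts65Dn and 55 passed the test, all of them higher. Of the 42 Mmu17 genes 38 had a higher mean and 25 passed, again all higher. The Mmu16 list mean of 22 of the 23 Ts65Dn arrays lay above that of every EupTs65Dn array, the exception being replicate 18.

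Among the Mmu16 genes, Atp5o and Atp5j, which encode subunits of mitochondrial ATP synthase, rose 1.4-fold (log2 0.48, SE 0.042, adjusted p = 1.2e-10) and 1.49-fold (adjusted p = 7.6e-09). The interferon receptor genes Ifngr2, Ifnar2 and Ifnar1 rose 1.44-fold, 1.5-fold and 1.33-fold. Genes of synaptic vesicle recycling rose too: Itsn1, an endocytic scaffold, 1.38-fold and Synj1, a phosphoinositide phosphatase, 1.38-fold. App, the amyloid precursor, rose 1.3-fold from a log2 mean of 10.93 to 11.31 (adjusted p = 6.5e-08). Dscam, an adhesion molecule of neurite self-avoidance, rose 1.39-fold and Paxbp1 1.41-fold. Sod1, which encodes cytosolic superoxide dismutase, rose 1.4-fold, the calcineurin inhibitor gene Rcan1 1.44-fold, the kinase gene Dyrk1a 1.32-fold, the calmodulin regulator gene Pcp4 1.33-fold and the ubiquitin ligase gene Ttc3 1.22-fold. The oligodendrocyte transcription factor gene Olig1 rose 1.23-fold (adjusted p = 0.066), while its neighbour Olig2 was at 1.17-fold without passing (adjusted p = 0.25). With the litter as a block Olig1 no longer passed (adjusted p = 0.14).

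Among the Mmu17 genes, Ezr, which encodes ezrin, a linker of membrane and actin, rose 1.47-fold (log2 0.56, SE 0.056, adjusted p = 4.4e-09). The ribonuclease gene Rnaset2a rose 1.48-fold, and Pde10a, a phosphodiesterase gene of striatal neurons, 1.39-fold (adjusted p = 1.3e-07). The dynein light chain genes Dynlt1b and Dynlt1c rose 1.37-fold and 1.33-fold. Gtf2h5, a subunit gene of the general transcription factor TFIIH, rose 1.4-fold, Tiam2, which activates the GTPase Rac, 1.4-fold, and Mpc1, which encodes a mitochondrial pyruvate carrier, 1.34-fold. Sft2d1 rose 1.43-fold, Scaf8 1.36-fold, the chromatin remodelling gene Arid1b 1.34-fold and Tulp4 1.31-fold. The sorting nexin gene Snx9 was at 1.33-fold without passing (SE of the log2 change 0.11, adjusted p = 0.12). Gpr31b, Unc93a, Tcp10b and Tcp10c, which lie beyond 1700010I14Rik in the gene order and were named after their values were seen, did not pass, with log2 changes of 0.20 (SE 0.11), 0.0018 (SE 0.12), 0.084 (SE 0.13) and 0.20 (SE 0.11). Where the extra dosage ends was not tested.

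Well expressed members, those at or above the median signal, showed the dosage most closely. The median fold was 1.35 over 60 such Mmu16 genes (quartiles 1.31 and 1.43), of which 54 passed, and 1.34 over 27 such Mmu17 genes (quartiles 1.31 and 1.4), of which 24 passed. The other 27 Mmu16 members had a median fold of 1.09, and 1 of them passed. Genes flanking the triplicated parts stayed near the euploid level: the mean of 14 Mmu16 flank genes differed by log2 -0.0032 (SE 0.038, permutation p = 0.93) and that of 12 Mmu17 flank genes by 0.023 (SE 0.020, permutation p = 0.24). Adjusted over the list alone, 67 Mmu16 genes and 31 Mmu17 genes were higher.

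**Figure D1:**
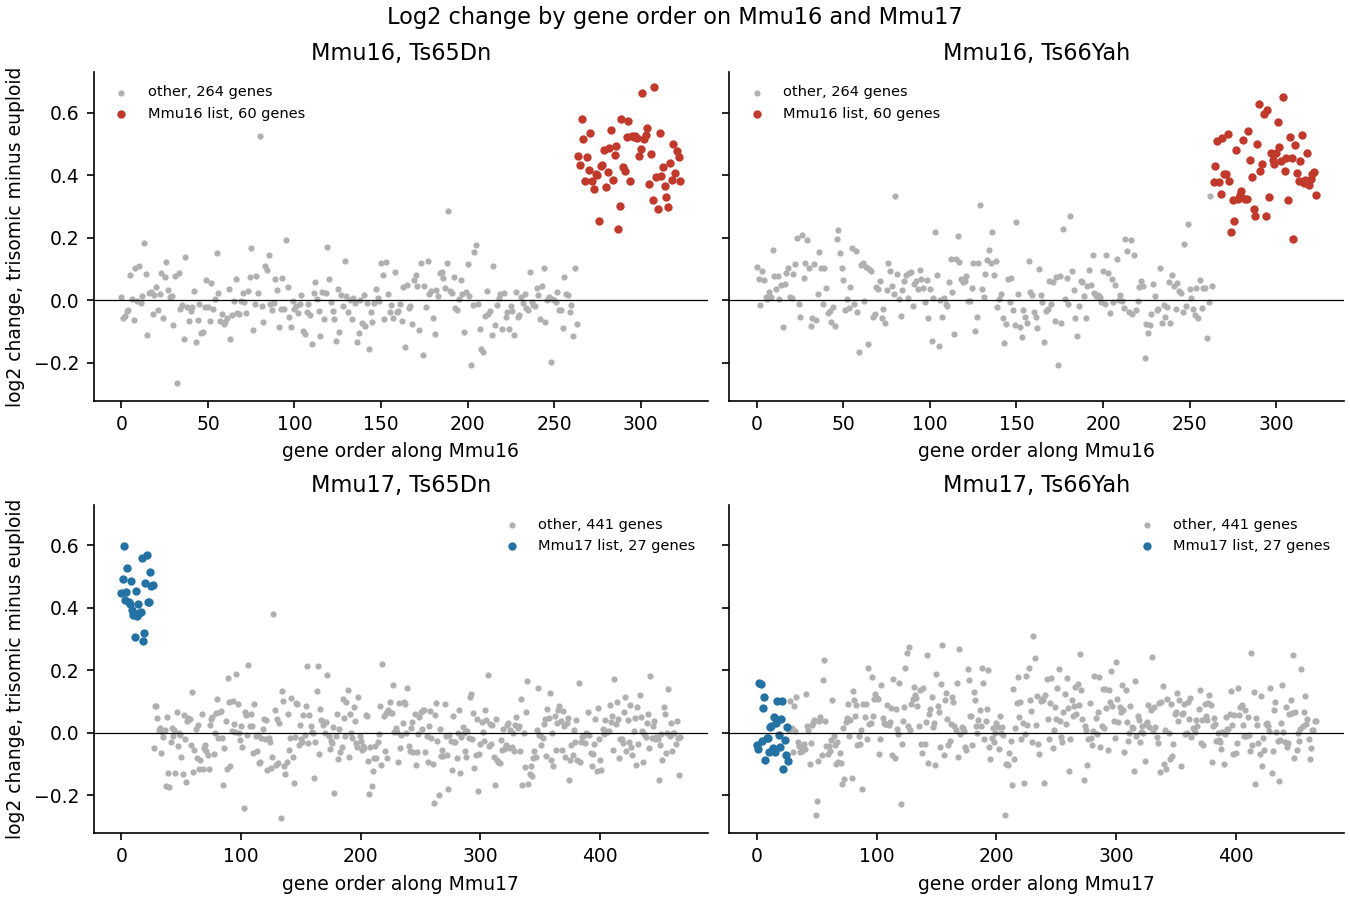
Log2 change (trisomic minus euploid) of each well expressed gene in its order along Mmu16 and Mmu17, for Ts65Dn (all arrays) and Ts66Yah (without the low-spread array); each point is 1 gene. The 60 Mmu16 list genes lie above 0 in both models, while the 27 Mmu17 list genes lie above 0 in Ts65Dn and around 0 in Ts66Yah.

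Outside the triplicated parts, 29 probe sets passed in Ts65Dn, 22 higher and 7 lower, of which 20 carried a gene name. Selenov, a selenoprotein gene, was the largest rise at 1.58-fold (log2 0.66, SE 0.14, adjusted p = 0.0062). Cdkl3, a kinase gene, rose 1.26-fold (adjusted p = 5.2e-05), Ifitm2, an interferon-induced transmembrane protein gene, 1.25-fold (adjusted p = 0.00019) and Antkmt, a mitochondrial lysine methyltransferase gene, 1.3-fold. Baz1a, a chromatin remodelling gene, rose 1.32-fold, Loxl3, a lysyl oxidase-like gene, 1.29-fold, and the dimmer genes Olfr203, Tcap, Vinac1 and Sytl5 1.4-fold, 1.38-fold, 1.38-fold and 1.33-fold. The 7 lower genes were Pla2g4c (0.646-fold), Rfx5, a regulator of MHC class II genes (0.706-fold), Ostn (0.760-fold), Trmt13 (0.812-fold), the transcription factor gene Deaf1 (0.839-fold, adjusted p = 0.00051), the cold-inducible RNA-binding protein gene Rbm3 (0.848-fold, adjusted p = 0.0039) and Pik3r3, a regulatory subunit gene of PI3 kinase (0.890-fold). Tcap and Trmt13 no longer passed with the litter as a block (adjusted p = 0.19 and 0.16), and centring each array on its median ended the calls of Tcap and Pik3r3 (adjusted p = 0.12 and 0.11).

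Of the cell type and pathway lists, the protocadherin beta cluster and the oligodendrocyte lineage stood out in Ts65Dn. Protocadherin beta genes, adhesion molecules that give neurons their surface identity, were lower: 17 of 20 measured members had a lower mean, the median log2 change was -0.20, and the list passed camera (adjusted p = 4.8e-07, and adjusted p = 0.017 with an estimated correlation). No member passed over all genes, with Pcdhb17 nearest at 0.833-fold (adjusted p = 0.11), and 7 were lower adjusted over the list alone. Per embryo the list mean fell by 0.15 on the log2 scale (SE 0.048, n = 18 and 23, permutation p = 0.0034), and 21 of 23 Ts65Dn embryos lay below the euploid median. Oligodendrocyte lineage markers, with the triplicated Olig1 and Olig2 left out, were higher: 13 of 15 had a higher mean, the median log2 change was 0.13, and the list passed (adjusted p = 0.0032, and adjusted p = 0.013 with an estimated correlation). None passed over all genes, with Gpr17, a receptor of oligodendrocyte precursors, nearest at 1.24-fold (adjusted p = 0.44), and 1 was higher adjusted over the list alone.

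The 7 other lists past the threshold in Ts65Dn did not hold with an estimated correlation, and 0 of their members passed over all genes. Of 45 cell cycle and mitosis genes 33 were lower (adjusted p = 0.0090, and adjusted p = 0.38 with an estimated correlation), with Nusap1, a spindle protein gene, at 0.903-fold. Lower means prevailed in cortical excitatory neuron markers (18 of 21, adjusted p = 0.091), GABAergic interneuron markers (13 of 19, adjusted p = 0.092), immediate early genes (12 of 18 probe sets, adjusted p = 0.092) and hypoxia and glycolysis genes (13 of 21, adjusted p = 0.091). With an estimated correlation their adjusted p-values were 0.42, 0.33, 0.33 and 0.55. Adjusted over the list alone, 3 hypoxia genes and 1 interneuron marker were lower. Higher means prevailed in nuclear oxidative phosphorylation genes (50 of 71, adjusted p = 0.031) and cytosolic ribosomal protein genes (43 of 56, adjusted p = 0.063), and their adjusted p-values with an estimated correlation were 0.71 and 0.72. With the litter as a block 3 lists passed: protocadherin beta, oligodendrocyte lineage, and cell cycle (adjusted p = 0.0010). The number of lists past the threshold was 2 without litter TS113, 5 without TS125 and 5 without TS42.

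The other 20 lists did not pass in Ts65Dn, with adjusted p-values from 0.14 to 0.99. They were the flanks of both triplicated parts, the Hsa21 orthologues on Mmu17 and Mmu10 that neither model triplicates, interferon response, radial glia, intermediate progenitor, striatal neuron, astrocyte, microglia, endothelial, pericyte and meningeal, erythroid, choroid plexus and ependymal, diencephalon, and midbrain and hindbrain markers, the unfolded protein, synaptic, Hedgehog, and Notch and Wnt lists, and the oxidative stress response. Among these, interferon response held 1 passing member, Ifitm2, which also passed adjusted over the list alone. Adjusted over the list alone, 2 choroid plexus and ependymal markers were higher and 2 lower, and 1 Notch and Wnt gene was higher and 1 lower. The median, the mean and the direction of camera did not share a sign for the astrocyte, microglia, choroid plexus and oxidative stress lists.

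In all, 109 of 22206 probe sets passed in Ts65Dn, 102 higher and 7 lower, by limma with Benjamini-Hochberg adjustment at 10%. The permutation p of both list means was 1e-05, the smallest that 100000 resamples can give.

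The second comparison put Ts66Yah against its euploid littermates, which asks what the Mmu16 part does without the Mmu17 genes. The Mmu16 genes were higher and the Mmu17 genes were not. The mean of the 87 Mmu16 genes was 7.58 ± 0.11 (SD, n = 24) in Ts66Yah and 7.20 ± 0.26 (n = 24) in EupTs66Yah, a 1.3-fold difference (log2 0.38, SE 0.058, permutation p = 1e-05, the smallest possible). It was 1.26-fold (log2 0.33, SE 0.033, n = 23 and 24) without the low-spread array. The mean of the 42 Mmu17 genes differed by log2 0.038 (SE 0.054, permutation p = 0.80), and by -0.014 (SE 0.016, permutation p = 0.39) without that array. Leaving out EupTs66Yah replicate 24, the Mmu16 list mean of 22 of the 24 Ts66Yah arrays lay above that of every euploid array, the exceptions being replicates 13 and 24.

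With all arrays 26 of the 87 Mmu16 genes passed, all higher, and without the low-spread array 59 did, all higher. Ifnar1 rose 1.37-fold (log2 0.46, SE 0.073, adjusted p = 0.00054) with all arrays and 1.33-fold (adjusted p = 4.6e-07) without it. Hunk, a kinase gene, rose 1.41-fold, Vps26c, an endosomal sorting gene, 1.46-fold, Smim11 1.48-fold, Cryzl1 1.39-fold and Cfap298 1.5-fold with all arrays. Il10rb, an interleukin receptor gene, rose 1.54-fold, the proteasome assembly gene Psmg1 1.33-fold, Ltn1, a ubiquitin ligase gene of ribosome quality control, 1.31-fold and Rcan1 1.43-fold. Dyrk1a rose 1.43-fold (adjusted p = 0.053) and did not pass with the litter as a block (adjusted p = 0.11). App was at 1.52-fold (adjusted p = 0.43), Sod1 at 1.4-fold (adjusted p = 0.28), Dscam at 1.51-fold (adjusted p = 0.28), Pcp4 at 1.46-fold (adjusted p = 0.24), Ttc3 at 1.32-fold (adjusted p = 0.49), and Olig1 and Olig2 at 1.29-fold and 1.42-fold, none of them passing with all arrays.

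Without the low-spread array those genes passed: App rose 1.27-fold (log2 0.34, SE 0.045, adjusted p = 1.7e-06), Sod1 1.26-fold (adjusted p = 5.1e-05), Dscam 1.32-fold, Dyrk1a 1.33-fold (adjusted p = 1.7e-07), Pcp4 1.31-fold, Ttc3 1.15-fold, Olig1 1.21-fold (adjusted p = 0.019) and Olig2 1.22-fold (adjusted p = 0.030). Atp5o rose 1.39-fold, Atp5j 1.42-fold, Ifnar2 1.42-fold, Smim11 1.4-fold, Hmgn1, a nucleosome-binding protein gene, 1.39-fold, the chaperonin gene Cct8 1.25-fold, and Dop1b and Pigp 1.37-fold each. Over the 60 well expressed Mmu16 genes the median fold was 1.33 (56 passing), against 1.44 (26 passing) with all arrays. Over the 27 well expressed Mmu17 genes it was 0.988 with 0 passing in limma, where 0 members also passed adjusted over the list alone. Named Mmu17 genes lay near 1-fold without that array: Pde10a at 0.939-fold, Scaf8 at 0.973-fold, Tulp4 at 0.988-fold, Snx9 at 1.08-fold and Arid1b at 1.11-fold. Adjusted over the list alone, 67 Mmu16 genes were higher and 1 lower with all arrays, and 69 were higher and 1 lower without the low-spread array. The flank lists differed by log2 0.031 (Mmu16, permutation p = 0.28) and 0.0071 (Mmu17, permutation p = 0.78), and by 0.081 and 0.082 with all arrays (permutation p = 0.14 and 0.39).

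**Figure D2:**
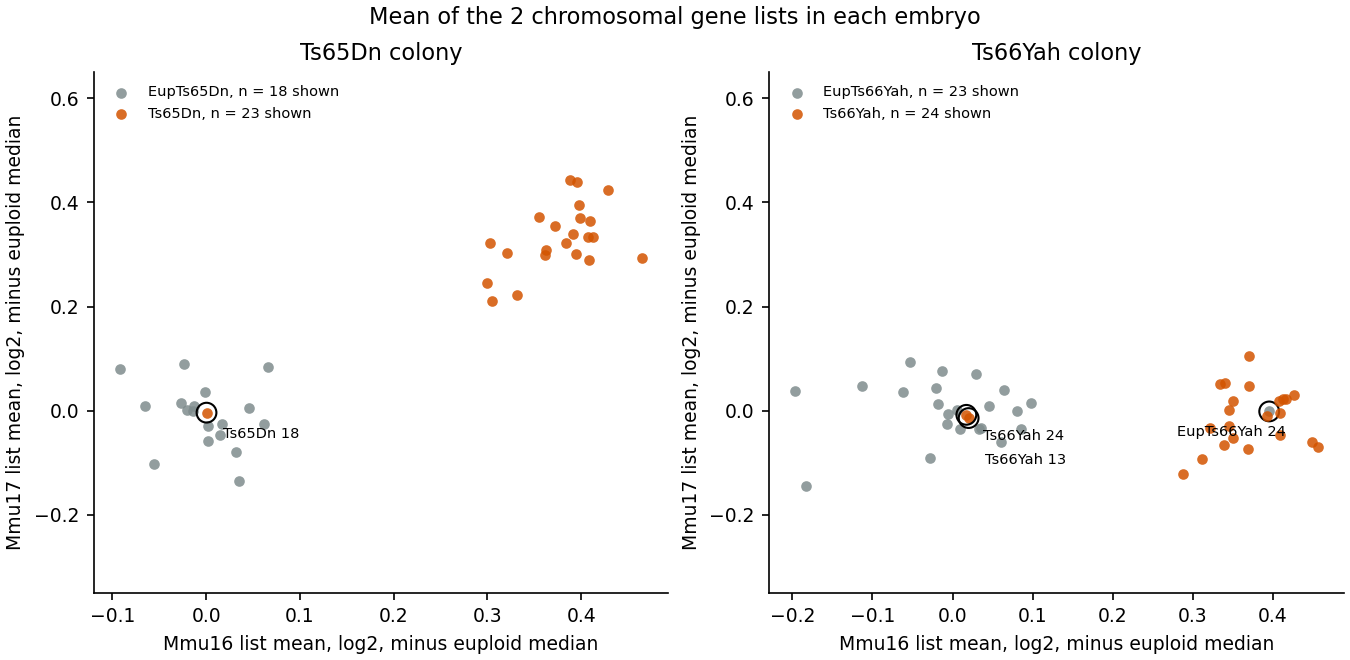
Mean log2 value of the Mmu16 list (horizontal) and of the Mmu17 list (vertical) in each embryo, minus the median of the euploid embryos of its colony; each point is 1 embryo, circles mark the 4 arrays at the level of the other genotype, and the low-spread array is not drawn. Ts65Dn embryos are displaced along both axes and Ts66Yah embryos along the Mmu16 axis.

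Outside the triplicated parts, 12 probe sets passed with all arrays, 10 higher and 2 lower, of which 8 carried a gene name, and all 8 were higher. Mbp, the myelin basic protein gene, rose 1.61-fold (log2 0.69, SE 0.17, adjusted p = 0.093) and Gjc3, a connexin gene of oligodendrocytes, 1.58-fold (adjusted p = 0.072). Selenov rose 1.60-fold, the growth factor gene Fgf15 1.37-fold, Plekhb1 1.36-fold, the cytokine gene Ltb 1.33-fold, the pyruvate dehydrogenase kinase gene Pdk2 1.27-fold and Igfbp7, a secreted binding protein of vessels, 1.24-fold. The calls of Gjc3, Fgf15, Plekhb1 and Igfbp7 ended with the litter as a block (adjusted p = 0.24, 0.13, 0.14 and 0.12). Those 4 and Mbp also ended with each array centred on its median (adjusted p = 0.13, 0.14, 0.11, 0.13 and 0.13). Mbp and Fgf15 ended with sex as a covariate as well (adjusted p = 0.11 for both). All 8 passed without the low-spread array, where Mbp was at 1.53-fold (adjusted p = 0.050) and Igfbp7 had an adjusted p of 0.0010. Mbp did not pass without the 6 narrower arrays (log2 0.57, adjusted p = 0.18) or, leaving out the low-spread array alone, with array spread as a covariate (log2 0.57, adjusted p = 0.19), and nor did Gjc3 (0.51 and 0.53, adjusted p = 0.21 for both). Pdk2 did not pass in the first of these settings (log2 0.22, adjusted p = 0.13) but did in the second (log2 0.27, adjusted p = 0.098).

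Without the low-spread array 148 probe sets outside the triplicated parts passed, 109 higher and 39 lower, and 128 of them carried a gene name. The 10 largest named rises were Gjc3 (1.59-fold), Selenov (1.59-fold), Slfn3 (1.56-fold), Anxa1, the annexin A1 gene (1.54-fold, adjusted p = 0.0061), Mbp, Msrb2 (1.51-fold), Ly96, a co-receptor gene of toll-like receptor signalling (1.49-fold), Aspa, an enzyme gene of oligodendrocytes (1.47-fold), Zfp92 (1.42-fold) and Rtl4 (1.41-fold). With the litter as a block in this setting the calls of Slfn3, Msrb2, Ly96, Aspa, Zfp92 and Rtl4 ended (adjusted p = 0.13, 0.15, 0.23, 0.15, 0.13 and 0.17). The 10 largest named falls, Olfr1465, Gm5169, Rhbdl2, Elf3, Gpr141, Gm765, Lypd8, Gm11238, Slc25a54 and Olfr645, lay between 0.682-fold and 0.757-fold. The calls of Gm5169, Gm765, Lypd8, Slc25a54 and Olfr645 ended with the litter as a block (adjusted p = 0.18, 0.11, 0.10, 0.13 and 0.12). All 10 of those falls were in dim probe sets, with means over all arrays from 2.45 to 3.73 against a median of 5.87 for the array. Without the 6 narrower arrays, with 18 euploid embryos left, 28 probe sets outside the triplicated parts passed, and 45 passed with array spread as a covariate. Of the 20 largest rises and falls Selenov and Anxa1 passed in both settings and Elf3 in the first.

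In Ts66Yah 16 of 29 lists passed camera without the low-spread array, all of them upwards, and 0 passed with an estimated correlation. In that setting 15 of 16 pericyte and meningeal markers had a higher mean, with a median log2 change of 0.15 (camera adjusted p = 1.1e-05, and adjusted p = 0.15 with an estimated correlation). Nupr1, a stress-induced nuclear protein gene, was the member that passed (1.25-fold, adjusted p = 0.085, and adjusted p = 0.11 with the litter as a block), and 8 were higher adjusted over the list alone. Per embryo the list mean was higher by 0.16 (SE 0.047, permutation p = 0.0015), above the euploid median in 20 of 24; it was 0.11 (SE 0.046, permutation p = 0.025) with array spread as a covariate and 0.10 (SE 0.045, permutation p = 0.029) without the 6 narrower arrays. Oligodendrocyte lineage markers were higher in 11 of 15 members (adjusted p = 0.0032, and adjusted p = 0.18 with an estimated correlation), with Mbp passing and 5 higher adjusted over the list alone. With the midbrain and hindbrain mean as a covariate their list mean was higher by 0.083 (SE 0.040) per embryo, against 0.14 without it. Endothelial markers were higher in 11 of 15 (adjusted p = 0.0032, and adjusted p = 0.20 with an estimated correlation), with Eng, an endothelial co-receptor gene (1.25-fold), and Ly6c1 (1.26-fold) passing, the latter not with the litter as a block (adjusted p = 0.16), and 5 higher and 1 lower adjusted over the list alone. Astrocyte markers were higher in 12 of 15 (adjusted p = 0.0032, and adjusted p = 0.29 with an estimated correlation) with 2 higher adjusted over the list alone. Midbrain and hindbrain markers had the largest median, 0.29, with 12 of 13 higher (adjusted p = 0.0032, and adjusted p = 0.29 with an estimated correlation), 0 passing and 1 higher adjusted over the list alone.

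In the same setting all 15 Hedgehog pathway genes and 22 of 28 Notch and Wnt genes had higher means (adjusted p = 0.0032 for both, and adjusted p = 0.15 for both with an estimated correlation), as did 34 of 45 cell cycle genes (adjusted p = 0.0032, and adjusted p = 0.29 with an estimated correlation), among them Aurkb, the Aurora B kinase gene (1.17-fold, adjusted p = 0.092, and adjusted p = 0.15 with the litter as a block). Radial glia markers passed (adjusted p = 0.040, and adjusted p = 0.29 with an estimated correlation) with the intermediate filament gene Vim at 1.14-fold (adjusted p = 0.085, and adjusted p = 0.12 with the litter as a block). Ribosomal proteins passed (adjusted p = 0.077) with Rps15 at 1.13-fold (adjusted p = 0.015), but the list did not pass with the litter as a block (adjusted p = 0.18) or with an estimated correlation (adjusted p = 0.65). The remaining lists that passed were interferon response, with Ifitm2 at 1.23-fold (adjusted p = 0.052), hypoxia and glycolysis, oxidative stress response, oxidative phosphorylation, synaptic genes, and the Hsa21 orthologues on Mmu17 and Mmu10. With an estimated correlation their adjusted p-values were 0.18, 0.25, 0.26, 0.49, 0.49 and 0.20. With the litter as a block the intermediate progenitor and immediate early lists passed as well (adjusted p = 0.098 for both). Adjusted over the list alone, 6 Notch and Wnt, 6 hypoxia, 3 synaptic, 3 Mmu17 and Mmu10, 2 radial glia, 2 ribosomal, 1 interferon and 1 cell cycle gene were higher and 1 synaptic gene lower, and of the Mmu16 flank 1 was higher and 2 lower. Centring each array on its median moved the median of all probe sets from 0.0044 to -0.040 and the means of the oxidative phosphorylation, ribosomal protein and synaptic lists to -0.0032, -0.019 and -0.0029, all above it.

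With an estimated correlation 0 of the 29 lists passed in Ts66Yah, where the adjusted p-values of the 16 passing lists ran from 0.15 to 0.65. Without the 6 narrower arrays 13 lists passed camera, all upwards, and with array spread as a covariate 12, of which 11 upwards; cell cycle, radial glia, synaptic, and Mmu17 and Mmu10 genes passed in neither. The calls of Olig1, Olig2, Nupr1, Eng, Ly6c1, Aurkb and Vim also ended in both settings. The directional fry test, which asks whether a list's members move one way on balance, called 13. The 13 lists that did not pass were the flanks, intermediate progenitor, cortical excitatory, GABAergic, striatal, microglia, erythroid, choroid plexus, diencephalon, immediate early, unfolded protein and protocadherin beta lists, among which erythroid and diencephalon markers had medians of -0.064 and -0.043. Protocadherin beta genes had a median log2 change of 0.019 (adjusted p = 0.58), which was -0.016 with quantile normalization and -0.025 with each array centred on its median, where the median of all probe sets was -0.040. Their list mean followed array spread closely (r = 0.833 within groups), and with spread as a covariate it was lower by -0.099 (SE 0.040, permutation p = 0.016; camera adjusted p = 0.0051, and adjusted p = 0.21 with an estimated correlation). The median, the mean and the direction of camera did not share a sign for the cortical excitatory, choroid plexus and Mmu17 flank lists. With all arrays 20 lists passed, 19 higher and 1, diencephalon markers, lower (adjusted p = 0.085), and their adjusted p-values with an estimated correlation ran from 0.40 to 0.55.

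In all, 38 probe sets passed in Ts66Yah with all arrays, 36 higher and 2 lower, and 207 without the low-spread array, 168 higher and 39 lower. Without the 4 arrays at the level of the other genotype as well, 326 passed. Without the 6 narrower arrays 76 passed, 48 of them Mmu16 genes, and 91, 46 of them Mmu16 genes, with array spread as a covariate and the low-spread array left out. Leaving out litter WT12 gave 15, leaving out WT15 gave 22, and leaving out WT18, the litter of the low-spread array, gave 88.

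**Figure D3:**
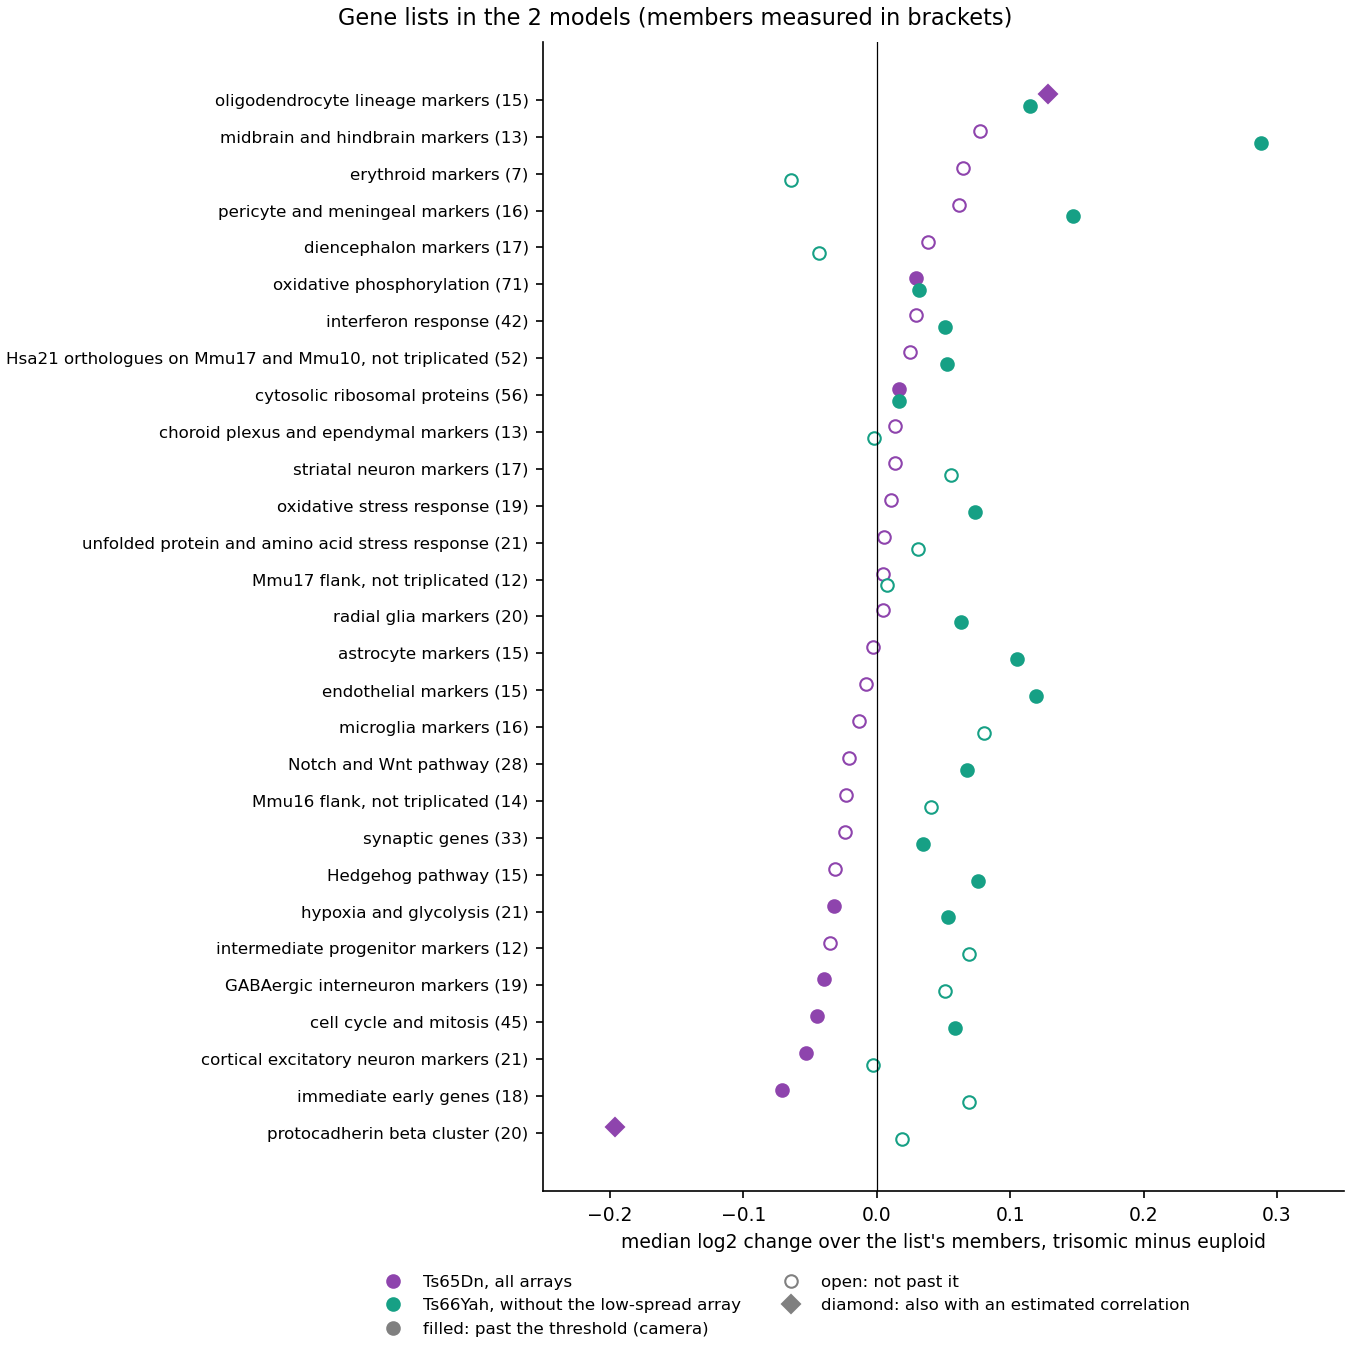
Median log2 change over the members of each of 29 gene lists in Ts65Dn (all arrays) and Ts66Yah (without the low-spread array); filled symbols passed camera and diamonds also passed with an estimated correlation. The protocadherin beta list lies at -0.20 in Ts65Dn and 0.019 in Ts66Yah, and the latter is -0.016 with quantile normalization and -0.025, above the -0.040 of all probe sets, with each array centred on its median; with array spread as a covariate the list is lower in Ts66Yah as well.

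The third comparison asked whether the effect of trisomy differs between the models, each against its own littermates. The Mmu17 genes separated them. With all arrays 2 genes passed, both in the Mmu17 list: Pde10a, changed by log2 0.53 more in Ts65Dn (SE 0.092, n = 89, adjusted p = 0.0020), and Cep43, a centrosomal protein gene, by 0.48 (SE 0.10, adjusted p = 0.065). Without the low-spread array 33 passed, 30 higher and 3 lower, of which 22 were Mmu17 genes, 0 Mmu16 genes and 11 others. Mpc1 differed by 0.44 (adjusted p = 2.3e-06), Sft2d1 by 0.58, Gtf2h5 by 0.50, Scaf8 by 0.49, Dynlt1b by 0.43, Rnaset2a by 0.47, Dynlt1f by 0.36, Tmem242 by 0.48 and Tulp4 by 0.41 (adjusted p = 0.012), while Arid1b and Snx9 differed by 0.27 and 0.30 without passing (adjusted p = 0.40 and 0.62). Adjusted over the list alone, 31 Mmu17 genes differed. With all arrays the count was 27 without litter WT18, and 1 without TS113, TS125, TS137, TS18, WT11, WT12, WT13, WT15 or WT19. The mean of the 42 Mmu17 genes differed by 0.34 without the low-spread array (permutation p = 1e-05, the smallest possible, adjusted p = 8.0e-05 over 8 lists) and by 0.29 with all arrays.

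The Mmu16 genes showed no detectable difference. Their list mean differed by 0.029 between the effects without the low-spread array (permutation p = 0.47) and by -0.019 with all arrays, and 0 of 87 passed in limma in either setting, with 0 adjusted over the list alone. At an unadjusted p under 0.05, 1585 of all probe sets differed without that array and 1565 with all arrays. All 60 well expressed Mmu16 genes had higher means in both models without the low-spread array, and 51 passed in both. Across these 60 genes the log2 changes correlated with a Pearson r of 0.515 and a Spearman rho of 0.443; genes are not independent replicates. Per gene, without the low-spread array, App differed by 0.041 (SE 0.060), Dyrk1a by -0.0080 (SE 0.068), Sod1 by 0.14 (SE 0.078), Rcan1 by 0.082 (SE 0.095), Dscam by 0.076 (SE 0.077), Pcp4 by 0.019 (SE 0.086), Ttc3 by 0.096 (SE 0.058), Olig1 by 0.033 (SE 0.097) and Olig2 by -0.063 (SE 0.098). With all arrays App differed by -0.22 (SE 0.29), Dyrk1a by -0.12 (SE 0.14), Sod1 by -0.0092 (SE 0.18), Rcan1 by 0.016 (SE 0.12), Dscam by -0.11 (SE 0.21), Pcp4 by -0.14 (SE 0.19), Ttc3 by -0.11 (SE 0.23), Olig1 by -0.067 (SE 0.15) and Olig2 by -0.28 (SE 0.25), so the signs of App, Sod1, Dscam, Pcp4, Ttc3 and Olig1 depend on that array.

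The protocadherin beta list mean was lower in Ts65Dn relative to Ts66Yah (difference -0.19, permutation p = 0.020, adjusted p = 0.032). The list passed camera for this difference (adjusted p = 0.00035) but not with an estimated correlation (adjusted p = 0.21). Without the 6 narrower arrays the difference was -0.091 (permutation p = 0.23), so it depends on arrays of low spread. In Ts65Dn alone the list mean was lower by -0.13 (SE 0.043, permutation p = 0.0051) with array spread as a covariate. That of oligodendrocyte markers did not differ detectably (-0.021, permutation p = 0.71). The difference for pericyte and meningeal markers was -0.12 (permutation p = 0.058, adjusted p = 0.078). These tests of list means ran on 8 lists without the low-spread array and were chosen after the lists had been seen.

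**Figure D4:**
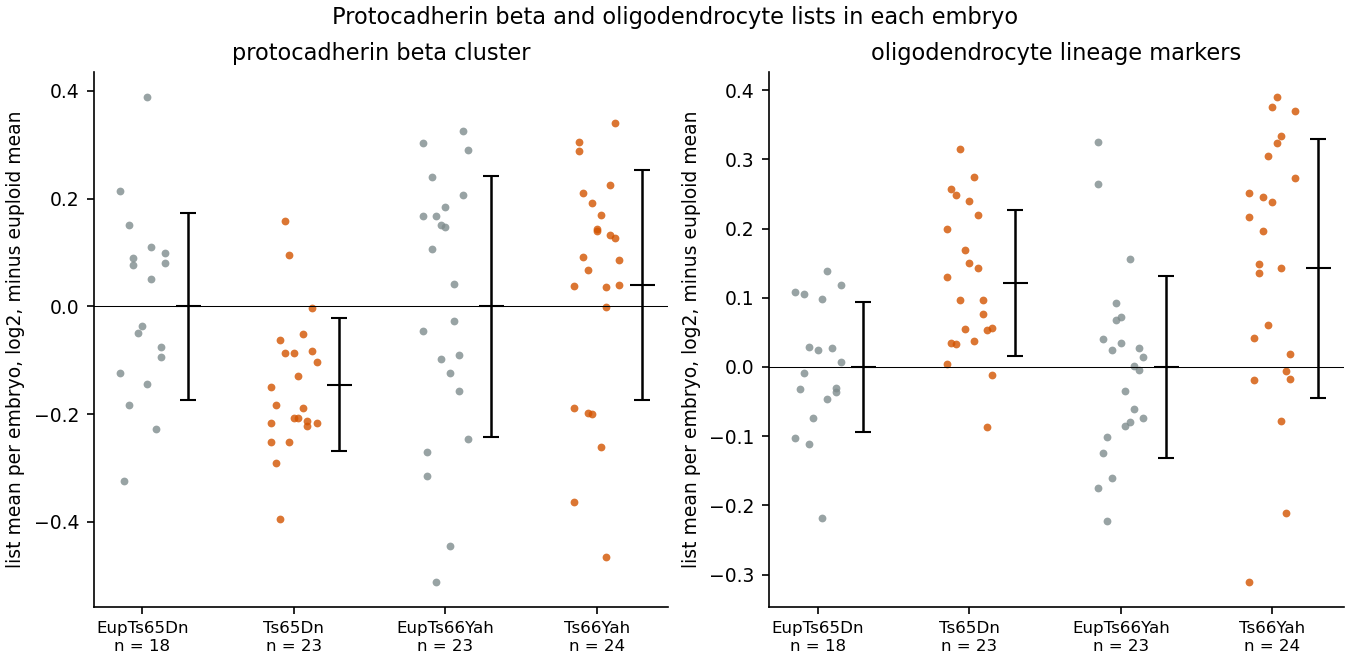
Mean log2 value of the 20 protocadherin beta genes and of the 15 oligodendrocyte lineage markers in each embryo, minus the euploid mean of its colony, with bars for the group mean and SD; each point is 1 embryo, without the low-spread array. For protocadherin beta 21 of 23 Ts65Dn embryos lie below the euploid median, and for oligodendrocyte markers 21 of 23 Ts65Dn and 18 of 24 Ts66Yah embryos lie above it.

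The calls that both models shared outside the triplicated parts were few. With all arrays Selenov alone was higher in both, against 0.0106 calls expected (Fisher's exact test, one-sided p = 0.016). Leaving out the low-spread array, 7 probe sets passed in the same direction in both, against 0.12 expected (Fisher's exact test, one-sided p = 7.3e-10). Antkmt, Cdkl3, Ifitm2 and Selenov were higher in both, Rbm3 and Pik3r3 lower in both, and 1 had no gene name. The expected numbers are for the same direction, while the Fisher test counts shared calls in either direction. It also takes probe sets as independent, which they are not, so its p-values do not measure the spread between embryos. In Ts66Yah without that array the log2 changes were 0.27 for Antkmt, 0.20 for Cdkl3, 0.30 for Ifitm2, 0.67 for Selenov, -0.21 for Rbm3 and -0.17 for Pik3r3. Leaving out the 6 narrower arrays, 4 probe sets were shared, Cdkl3, Rfx5 and Selenov among them. With array spread as a covariate in both models, and without the low-spread array, 8 were shared, those 3, Idh2, Ifitm2, Pik3r3 and Rbm3 among them. With all arrays Rbm3 did not pass in Ts66Yah and lay at 0.14. The Spearman rho of the log2 changes across all probe sets outside the triplicated parts was 0.060 without that array, and 0.18 across the 11016 of them at or above the median signal, a description across genes and not across animals.

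The fourth comparison set the euploid embryos of the 2 colonies side by side, to measure how far the colonies differ without trisomy. The median log2 difference of all probe sets, EupTs65Dn minus EupTs66Yah, was -1.05 (n = 18 and 24), so changes are given relative to it. Among the lower genes were Tfap2b, a transcription factor gene (-3.10 beyond the median), and Mab21l2, a gene of the developing midbrain and eye (-2.49). Mab21l2 had a log2 mean of 6.21 ± 0.46 (SD, n = 18) in EupTs65Dn and 9.74 ± 0.80 (n = 24) in EupTs66Yah (adjusted p = 2.2e-19). Slc6a5, the glycine transporter gene of inhibitory neurons of the hindbrain and spinal cord, Psg23, a pregnancy-specific glycoprotein gene, and Prl8a6, a prolactin family gene, had means of 6.52 ± 0.73, 5.61 ± 1.90 and 5.44 ± 1.83 (SD, n = 24) in EupTs66Yah. Their means in EupTs65Dn, 2.87, 1.69 and 1.82, lay under the lower quartile of all probe sets (3.80), so no exact difference is given for them. That quartile is of means over the arrays of both colonies, and the Ts65Dn colony lay at a lower level. How dim these genes are within that colony was not tested. The 5 named genes with the largest rises were Dlx5 and Isl1, transcription factor genes of ventral forebrain neurons (1.91 and 1.85 above the median), Rnps1 (1.68), Miat (1.63) and Fezf1, a forebrain transcription factor gene (1.55).

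All 13 measured midbrain and hindbrain markers lay below the median of all probe sets in EupTs65Dn (camera adjusted p = 7.4e-06, and adjusted p = 0.10 with an estimated correlation). Without the low-spread array all 13 again lay below it (adjusted p = 0.16, and adjusted p = 0.67 with an estimated correlation). Their list mean in EupTs65Dn, 3.48, lay under the lower quartile of all probe sets (3.80), so no exact difference is given. Since that quartile is over the arrays of both colonies, it does not show that the markers were dim within the Ts65Dn colony. With all arrays 11 of 29 lists passed and 0 with an estimated correlation. Leaving out the low-spread array 10 passed, and 5 also with an estimated correlation: intermediate progenitor (median 0.53 relative to all probe sets, adjusted p = 0.0046), GABAergic interneuron (0.33, adjusted p = 0.034) and diencephalon markers (0.064, adjusted p = 0.045), immediate early genes (0.23, adjusted p = 0.045) and interferon response (-0.0087, with camera's direction upwards, adjusted p = 0.042). These list tests were chosen after the named genes had been seen. Camera divides each gene's change by its spread, and here almost every change holds the shift of all probe sets. Its calls in this comparison therefore do not measure change relative to the median, those of the midbrain and hindbrain markers included. Without the low-spread array 56 ribosomal protein genes had a median 0.36 above that of all probe sets, but camera's direction was downwards (adjusted p = 0.051). Of 22206 probe sets 21703 passed, 20 higher and 21683 lower, the Mmu16 and Mmu17 genes among them (85 of 87 and 41 of 42, all lower). With quantile normalization over both groups 5723 passed, 3020 higher and 2703 lower. Strain, litter, dissection and array processing cannot be told apart in this comparison.

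The fifth and sixth comparisons asked whether the effect of trisomy differs between males and females in each colony. No gene passed in limma in either: 0 in the Ts65Dn colony, with 941 at an unadjusted p under 0.05, and 0 in the Ts66Yah colony, with 931. The unpaired t-test also gave 0 in both. The first principal component of the residuals as a covariate gave 5435 in the Ts66Yah colony. That component comes from the residuals of the same model, so it leaves each estimated effect unchanged and only narrows the residual spread. The count of 5435 therefore does not speak for an interaction. The Y-linked genes Kdm5d, Uty and Eif2s3y went against the sex label in 17 arrays, 8 in the Ts65Dn colony and 9 in the Ts66Yah colony: 11 arrays labelled female had the Y-linked signal and 6 labelled male lacked it. The 11 include the low-spread array, whose compressed values leave this check uninformative for it. Without those arrays the count was again 0 in each colony. In simulated data of these sizes the test found 72% of 1.5-fold interactions in the Ts65Dn colony and 76% in the Ts66Yah colony without the low-spread array, and 22% and 42% of 1.3-fold ones, so most interactions of 1.3-fold would be missed with these numbers of embryos. The simulation took every sex label as right and changed only probe sets at or above the median signal. Its shares may therefore overstate what the test could find in the data, where the Y-linked genes went against the label in 17 arrays.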

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

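The tests without the low-spread array or the 6 narrower arrays, those with array spread as a covariate, the tests of mixture and exchange of arrays, the tests of signal level, neurons, litters, and ribosomal and oxidative phosphorylation genes, and the differences of list means were chosen after the results had been seen.

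The trisomy effects of the models differed for the following genes and lists by a test of the difference itself (Ts65Dn minus Ts66Yah). With all arrays the Mmu17 genes Pde10a and Cep43 differed by log2 0.53 (SE 0.092, adjusted p = 0.0020) and 0.48 (SE 0.10, adjusted p = 0.065), as the absence of the Mmu17 part from Ts66Yah entails. The Mmu17 list mean differed by 0.34 without the low-spread array (adjusted p = 8.0e-05 over 8 lists). In the same setting, outside the triplicated parts, Speer4f1 differed by 0.72 (SE 0.17, adjusted p = 0.056), the olfactory receptor gene Olfr782 by 0.72 (SE 0.17, adjusted p = 0.056), Baz1a by 0.48 (SE 0.12, adjusted p = 0.086) and Dnaaf6b, a gene of dynein arm assembly, by 0.45 (SE 0.11, adjusted p = 0.072). Ostn differed by -0.62 (SE 0.14, adjusted p = 0.023), Map3k11, a kinase gene, by -0.68 (SE 0.17, adjusted p = 0.072) and Hapln4, a link protein gene of the perineuronal matrix, by -0.61 (SE 0.15, adjusted p = 0.088). Baz1a rose in Ts65Dn (log2 0.40) and lay at -0.080 in Ts66Yah without passing, while Hapln4 rose in Ts66Yah (0.48) and lay at -0.13 in Ts65Dn without passing. With the litter as a block in that setting the calls of Olfr782, Baz1a, Dnaaf6b and Ostn ended (adjusted p = 0.16, 0.16, 0.23 and 0.10). Without the 6 narrower arrays only Ostn and Hapln4 passed, and with array spread as a covariate only Ostn. Speer4f1, Olfr782, Dnaaf6b and Ostn had means over all arrays under the lower quartile (3.80), so their values are not exact. With all arrays none of these 7 passed, with adjusted p-values of 0.47 for Speer4f1, Olfr782, Baz1a, Dnaaf6b and Map3k11, 0.66 for Hapln4 and 0.65 for Ostn.

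The Hedgehog pathway list, genes of the signal that patterns the ventral forebrain, had a median difference of -0.17 without the low-spread array, with 12 of 15 members lower in Ts65Dn relative to Ts66Yah. It passed camera with the preset correlation (adjusted p = 0.0014) and with an estimated correlation (adjusted p = 0.048). With all arrays it passed with the preset correlation (adjusted p = 0.0042) and not with an estimated correlation (adjusted p = 0.15), so the latter call depends on leaving out 1 array. The latter did not pass without the 6 narrower arrays (adjusted p = 0.11) or with array spread as a covariate (adjusted p = 0.19) either. In Ts65Dn alone its median was -0.032, and in Ts66Yah alone, without that array, 0.076.

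In 4 arrays the Mmu16 list mean lay at the level of the other genotype, and a wrong label may account for each. At least 81.7% of the 60 well expressed Mmu16 genes lay nearer to the other genotype in each of these arrays, and in the array labelled Ts65Dn replicate 18 so did 92.6% of 27 Mmu17 genes. A mixture of euploid and trisomic RNA is argued against, since 0 of the 4 arrays lay between the genotypes. For the arrays labelled Ts66Yah replicate 13 and Ts65Dn replicate 18 a swap within the litter is argued against, since these 2 had no partner out of place, while an exchange of the arrays labelled Ts66Yah and EupTs66Yah replicate 24 in litter WT19 cannot be told apart from separate errors: the Y-linked genes of 1 of the pair go against the sex label of the other, but sex labels fail in 17 arrays anyway. No biological explanation was tested.

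Pericyte and meningeal markers were higher in Ts66Yah, and a change of vessels or meninges with the genotype may be the source. The low-spread array is argued against as the whole cause, since the list passed without it (camera adjusted p = 1.12e-05), and so is a shift of bright against dim probe sets, since it passed among probe sets at or above the median signal (adjusted p = 0.00228). Array spread is argued against as the whole cause by its use as a covariate (permutation p = 0.0249), though the difference fell from 0.16 to 0.11, and 6 euploid arrays were narrower than every Ts66Yah array, so a part of it goes with spread. Carry-over of meninges that varies between embryos regardless of genotype is argued against by the permutation over embryos (p = 0.00152, higher in 20 of 24). This p is unadjusted for the choice of the list as well, so it argues only weakly. Carry-over that went with the genotype stays open, as does a biological difference, and with an estimated correlation the list did not pass (adjusted p = 0.15).

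Protocadherin beta genes were lower in Ts65Dn. A test of an effect that Ts66Yah does not share, without the low-spread array, spoke for such an effect (permutation p of the difference = 0.0200). That test was chosen after the lists had been seen. Without the 6 narrower arrays the test did not speak for it (permutation p = 0.229, difference -0.091). An effect of Ts65Dn alone and one of both models therefore cannot be told apart. For fewer neurons, the mean of 90 neuronal and synaptic genes changed by -0.023, and its interval ended at -0.051, above the protocadherin beta list mean of -0.15. The interval of the protocadherin beta list, -0.24 to -0.049, meets that of the neuronal genes. The 2 changes were not tested against each other, so fewer neurons stay open. Across the embryos of a group the list mean ran against those of ribosomal protein and oxidative phosphorylation genes (r = -0.39 and -0.34, and -0.64 and -0.62 in the Ts66Yah colony), but a shift that raises these genes is argued against as the whole cause, since with both means as covariates the difference was -0.13 in Ts65Dn (SE 0.044, permutation p = 0.00456), and 0.085 in Ts66Yah (SE 0.052, permutation p = 0.11) against 0.040 without them. With the litter as a block the list passed camera with the preset correlation (adjusted p = 7.07e-06). In that setting 44 of 100 splits within litters gave as many passing lists as the real 3 (highest other 9). That p therefore cannot decide about unequal litters, which stay open. Array spread as the whole cause is argued against by its use as a covariate in Ts65Dn (permutation p = 0.00509). Spread between embryos is argued against by the permutation (p = 0.00341, lower in 21 of 23). Signal shared between these closely related genes was not tested and stays open, so the 20 members cannot be counted as 20 separate measurements.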

How the results depend on the processing

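The settings without the low-spread array, without the doubted arrays (that array and the 4 at the level of the other genotype), without the 6 narrower arrays, with array spread as a covariate, and the pairs of settings built on these were chosen after seeing the data. The Mmu16 mean kept its direction and passed under 14 alternatives in Ts65Dn (0.272 to 0.446) and 16 in Ts66Yah (0.244 to 0.521), and the Mmu17 mean under 15 in Ts65Dn (0.224 to 0.443). In Ts66Yah the Mmu17 mean passed under none of 17; it was -0.0165 with each array centred on its median, which moves every gene alike, turned negative without the low-spread array (-0.0138) , without the doubted arrays (-0.0140) and without the 6 narrower arrays (-0.0203), and lay between -0.0170 (without litter WT18) and 0.0556 (without WT19) with 1 litter left out. The Ts65Dn count of 109 stayed within 1.5 times under 20 of 22 alternatives (leaving out 1 litter gave 93 to 116), and became 246 by the marginal criterion of the series and 68 with all 4 groups in 1 fit. The Ts66Yah count of 38 stayed so under 13 of 26. It was 472 by the marginal criterion, 158 with array weights, 7219 with the first principal component, 210 with all groups in 1 fit, 207 without the low-spread array, 326 without the doubted arrays, 279 with array spread as a covariate, 76 without the 6 narrower arrays, 91 without the low-spread array and with array spread as a covariate, 156 without the low-spread array and with the litter as a block, and 15 (without WT12) to 88 (without WT18) with 1 litter left out, WT15 giving 22. The difference count of 2 was 1 at a threshold of 0.05, 312 by the marginal criterion, 7 with quantile normalization, 29 with array weights, 3344 with the first principal component, 33 without the low-spread array, 34 without the doubted arrays, 35 with array spread, 29 without the 6 narrower arrays, 30 without the low-spread array and with array spread as a covariate, 29 without that array and with the litter as a block, and 1 to 27 (without WT18) with 1 litter left out. The euploid count of 21703 was 10616 above the median signal, where fewer probe sets were tested, 5723 with quantile normalization and 10714 with each array centred on its median, which take out the level of the colonies. The sex counts of 0 became 179 (Ts65Dn colony) and 145 (Ts66Yah colony) by the marginal criterion, which adjusts for no multiple testing, and 5435 (Ts66Yah) with the first principal component. The 9 lists of Ts65Dn became 2 with an estimated correlation, 2 by fry, 3 with the litter as a block, and 2 (without TS113) to 11 (without TS137) with 1 litter left out, 5 without TS125 and 5 without TS42. The 20 lists of Ts66Yah became 0 with an estimated correlation, 3 by fry, 12 above the lower quartile and 10 with array spread; without the low-spread array they became 0 with an estimated correlation, 13 by fry, 6 above the median signal and 12 with array spread as a covariate, and without the 6 narrower arrays 13. The shared count of 1 was 22 at unadjusted p under 0.01, 2 by the t-test, 7 without the low-spread array, 9 without the doubted arrays, 4 without the 6 narrower arrays, and 8 without the low-spread array and with array spread as a covariate. Where no construction is named, the cause was not tested. The first principal component is taken from the residuals of the same model. It leaves each estimated effect unchanged and only narrows the residual spread, so the larger counts with it do not show more changed genes. Of 75 named genes in Ts65Dn the litter as a block ended 3 calls and began 1, that of the hypoxia gene Ddit4 (log2 -0.23, adjusted p = 0.065), and of 59 in Ts66Yah it ended 5. Without the low-spread array it ended 15 of 45 calls of named genes in Ts66Yah and 4 of 18 in the difference. In Ts66Yah, of these 45 calls 25 ended without the 6 narrower arrays and 25 with array spread as a covariate, and in the difference 5 and 6 of 18; 5 euploid arrays fewer are a part of the first. The calls the litter ended are given beside their genes; it changed no other call of the named genes, and with all arrays no called gene turned its sign. The litter with sex as a covariate was not run for the sex results, whose model holds sex already. Dim probe sets limit what the arrays show: 1 of the 27 Mmu16 genes under the median signal passed in Ts65Dn, against 54 of the 60 others.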

Other observations

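The differences of list means, the lists in the difference of effects, the list means with other list means or array spread as covariates, those without the 6 narrower arrays, the splits of lists within litters and the splits without the low-spread array were chosen after the results had been seen.

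The list means without the low-spread array differed (Ts65Dn minus Ts66Yah) by -0.15 for 21 hypoxia genes and -0.16 for 15 Hedgehog genes (adjusted p = 0.00091 for both over 8 lists) and by -0.12 for 45 cell cycle genes (adjusted p = 0.0084). By camera with an estimated correlation the difference passed for the Hedgehog genes (adjusted p = 0.048) and not for the hypoxia and cell cycle genes (adjusted p = 0.13 for both). Without the doubted arrays it passed for the Hedgehog (adjusted p = 0.024) and hypoxia genes (adjusted p = 0.062) and not for the cell cycle genes (adjusted p = 0.20). Without the 6 narrower arrays the differences of list means were -0.13 for hypoxia (permutation p = 0.0022), -0.12 for Hedgehog (permutation p = 0.0061) and -0.068 for cell cycle genes (permutation p = 0.081). Per embryo the cell cycle mean was lower by -0.050 in Ts65Dn (SE 0.032, permutation p = 0.10, below the euploid median in 15 of 23) and higher by 0.074 in Ts66Yah (SE 0.033, permutation p = 0.027, above it in 20 of 24). The latter went with array spread (r = 0.646 within groups): it was 0.021 (SE 0.027, permutation p = 0.43) with spread as a covariate and 0.018 (SE 0.026, permutation p = 0.49) without the 6 narrower arrays. Oligodendrocyte markers were higher by 0.12 in Ts65Dn (SE 0.031, permutation p = 0.00048, above in 21 of 23) and 0.14 in Ts66Yah (SE 0.047, permutation p = 0.0045, above in 18 of 24), and with spread as a covariate by 0.11 (permutation p = 0.00064) and 0.13 (permutation p = 0.012). Midbrain and hindbrain markers were higher too, by 0.078 in Ts65Dn (SE 0.036, permutation p = 0.044, above in 18 of 23) and 0.30 in Ts66Yah (SE 0.14, permutation p = 0.042, above in 19 of 24), but with spread as a covariate by 0.061 (permutation p = 0.072) and 0.26 (permutation p = 0.099). Across the embryos of a group the oligodendrocyte mean followed that of these region markers in the Ts66Yah colony (r = 0.607), with r = 0.152 in the Ts65Dn colony. With the region markers as a covariate the oligodendrocyte difference was 0.11 in Ts65Dn (SE 0.033, permutation p = 0.0019) and 0.083 in Ts66Yah (SE 0.040, permutation p = 0.043). In the Ts65Dn colony the region markers lay at 3.48 and 3.56, under the lower quartile of 3.80 over the arrays of both colonies. That colony lay at a lower level, so how dim they are within it was not tested. With r = 0.152 there, the covariate can take out little. Pericyte and meningeal markers differed by 0.033 in Ts65Dn (SE 0.046, permutation p = 0.48). Camera called 14 of 29 lists in the difference, all lower in Ts65Dn relative to Ts66Yah, 1 of them with an estimated correlation, and fry called 4.

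The array labelled Ts65Dn replicate 18 lay at 0.082 of the way from the euploid to the trisomic median of its Mmu16 genes and at 0.076 for its Mmu17 genes. The arrays labelled Ts66Yah replicates 13 and 24 lay at 0.024 and -0.049, and that labelled EupTs66Yah replicate 24 at 0.984. Leaving out the low-spread array, whose Mmu16 list mean was 6.08, the other arrays lay between -0.24 and 0.21 (EupTs65Dn), 0.79 and 1.12 (Ts65Dn), -0.62 and 0.31 (EupTs66Yah), and 0.70 and 1.11 (Ts66Yah). The Y-linked signal was present in 2, 2, 5 and 2 arrays labelled female in EupTs65Dn, Ts65Dn, EupTs66Yah and Ts66Yah, and absent from 2, 2, 2 and 0 labelled male. The low-spread array is 1 of the 5, and its compressed values leave this check uninformative for it.

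Each count was set against 100 splits of the arrays, the real one included. No other split reached the counts of Ts65Dn (109 probe sets, highest other split 3), Ts66Yah (38, highest other 1) or the difference of effects (2, highest other 1). Triplicated genes made up most of them: 55 Mmu16 and 25 Mmu17 genes in Ts65Dn, 26 Mmu16 genes in Ts66Yah, and 2 Mmu17 genes in the difference. The adjustment runs over all probe sets together, so splits that mix the genotypes do not test the calls outside these lists apart. For the lists in Ts66Yah 3 of the 100 splits gave as many as the real 20 (highest other 20). Such a count was rare but within reach of chance. Without the low-spread array the splits did not reach 207 in Ts66Yah (highest other 3) or 33 in the difference (highest other 3) either. No other split reached the 16 lists (highest other 13). The 99 splits drawn apart for the shared calls in that setting went higher in the Ts66Yah colony. They gave up to 111 probe sets outside the triplicated parts, against the real 148. The highest split thus depends on the draw, so such counts were rare, and chance is not excluded. Splits made within litters did not reach the counts of Ts65Dn (109, highest other 3) or Ts66Yah (38, highest other 0). For the lists in Ts66Yah without the low-spread array 2 of these splits gave as many as the real 16 (highest other 17), so that count too was within reach of chance. With the litter as a block as well, no other split reached the real 17 (highest other 13). The 9 lists in Ts65Dn exceeded the other splits (highest other 8) and were reached by 2 splits within litters (highest other 9), but with the litter as a block 44 of the 100 splits within litters gave as many as the real 3 (highest other 9), so chance cannot be excluded for that count. For the euploid groups no other split reached the real count (21703, highest other 15105). A split that calls so many points to a structure of the arrays, which the level of the colonies gives. For genotype by sex the splits decide nothing, because all 100 reach a count of 0 whatever the data (highest other 8 in the Ts65Dn colony and 5 in the Ts66Yah colony). They decide nothing for the shared calls either (1 with all arrays and 7 without the low-spread array, highest other 0 for both): calls outside the triplicated parts were made in both colonies in 0 of the 99 other splits with all arrays and in 1 of 99 without that array, so hardly any split had calls to share.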
